A study of Homo sapiens with 4 samples.

How the data were processed

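Total RNA of MCF7 cells was made into strand-specific libraries and sequenced in pairs on an Illumina HiSeq, per the labels' protocols. The cells had grown with 10% FBS, spent 3 days in stripping medium free of phenol red and then 6 h with or without E2. The labels' protocols give the dose as 1e-07 M, and the treatment label of the E2 sample writes the exponent without its minus sign; the protocol was followed. Whether linear RNA was removed before library preparation is not given in the sources used here. Groups came from the treatment labels, with 1 circRNA library for DMSO and 1 for E2. A further 2 RNA-seq samples, with control or circPGR siRNA, were not analysed here.

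The submitters' processing notes name CASAVA 1.4, TopHat2 2.1.1 and the build hg19 (GRCh37), with no roles. The circRNA caller is not given in the sources used here. Per the file headers, the deposited tables give for each circRNA its chromosome, start, end, strand, type, host gene, back-splice read count and linear (non-junction) read count. They also hold a deposited fraction, the junction read ratio, which equalled 2 times the back-splice reads over that number plus the linear reads to within 0.0005. The smallest deposited count was 2, so an unlisted circRNA had 0 or 1 read only if nothing else kept it off the list, which the sources used here do not say. The names of the reads in each row equalled the count in every row, no read was listed for more than 1 circRNA, and the reads of both libraries carried the name of 1 flow cell lane each. Coordinates and gene symbols are those of the tables, in hg19. No annotation of that build was used, so exons are not numbered.

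Reads were taken as shares of each library's back-splice reads. A circRNA was identified by chromosome, start, end and strand, and its ratio is the E2 share over the DMSO share with an exact 95% conditional (Clopper-Pearson) interval. For an unlisted circRNA the ratio was computed at a floor of 3 reads (0.00101% of the back-splice reads in DMSO and 0.000859% in E2) and given as a bound, and the interval at 1 read; both hold only if the circRNA had 0 or 1 read. With 1 library per group no p-value, SE or test across conditions was made. A fixed rule of size set circRNAs and host gene sums apart: 10 or more reads over both libraries, a ratio of 2 or more or of 0.5 or less, and an interval that excludes 1. Every circRNA of 10 or more reads that is listed in 1 library passes this rule by its construction. Intervals of medians come from order statistics. Each list's median was placed among 10000 random lists of the same size matched on reads.

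Host gene symbols were those listed for a circRNA, and where several were listed they were kept together as 1 name. In a host gene sum an unlisted circRNA added no reads. Only a sum without any listed circRNA in a library was set to the floor. Per host gene, linear reads were taken from the circRNA listed in both libraries with the most linear reads, at most 10000, which shares no end with a circRNA of 20 or more reads listed in 1 library. Linear reads were scaled by the median ratio of host genes with 20 or more linear reads, 1.06. Total linear reads were 112582375 in DMSO and 118281751 in E2, but 98.8% and 98.6% of these lay at 19 and 20 circRNAs with over 10000 linear reads, so their sum says little about depth.

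The groups, the rule of size, the gene lists, the named items and the first set of alternative settings were fixed before the data were examined. Named items were every PGR circRNA with 2 or more reads, the 8 circRNAs per direction whose interval bound nearest to 1 was farthest from 1, the 4 host gene sums per direction with the most reads past the rule and not yet named, per list the 3 host genes with the most reads and at most 4 more past the rule, and the 5 circRNAs with the most reads. The lists were estrogen-induced genes, estrogen-repressed genes, cell cycle genes, known circRNA hosts, luminal identity genes, genes of the 17q23 and 20q13 regions, genes of microRNA, RNA-binding and circRNA-forming proteins, immune cell markers, stromal, mesenchymal and basal markers, and abundant noncoding and other linear RNAs. The 8 circRNAs per direction among those listed in both libraries, the linear choices and the examples so marked were added after seeing the data.

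The rule was tested on simulated data. Poisson counts were drawn for 34116 circRNAs at the means and library sizes of the comparison of E2 with DMSO. Only circRNAs with 2 or more reads were listed, and no other spread between libraries was simulated. Over 20 simulations without change, 133 circRNAs passed as higher and 139 as lower. Of 200 circRNAs changed 4-fold, 52.0% were recovered at means of 10 to 19 reads, 85.0% at 20 to 49 and 99.5% at 50 or more. Of those changed 2-fold, 14.5%, 33.5% and 48.0% were. The interval held the true ratio for 95.9% of unchanged circRNAs with 50 or more reads. A list of 30 host genes raised 1.5-fold lay at percentile 100, and 20 unchanged lists had a mean percentile of 51.5.

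The alternatives fixed then were other minimum counts, thinning of the E2 library to the DMSO total (100 draws), ends matched within 5 bases, scaling by the median ratio, by edgeR TMM factors or by total linear reads, ratios of 1.5 and 3, a 99% interval, exonic circRNAs only, and no unplaced sequences. Added after seeing the data were circRNAs listed in both libraries only, 0 reads for an unlisted circRNA in the interval, reads of 1 circRNA within 100 position units on 1 tile counted once, and for linear reads scaling by their sum, inclusion of shared ends and a minimum of 50 reads. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 for TMM factors only.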

Results

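Circular RNAs (circRNAs) of MCF7 cells, an established estrogen receptor-positive breast cancer line, were sequenced to find the circRNA program induced by estrogen. The cells had spent 3 days in stripping medium before 6 h with vehicle (DMSO) or estradiol (E2, 1e-07 M). There was 1 library per condition, so no difference between them could be set against a spread between replicates. The ratios below compare these 2 libraries, and their intervals cover counting error only. Reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for that. Each circRNA was identified by its back-splice junction, the site where the end of an exon or intron is joined to a position upstream of it. The DMSO library held 297846 back-splice reads and the E2 library 349160, which was 17.2% more.

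How many circRNAs the cells carried, and how many of them were seen in both conditions, was compared first. The DMSO library listed 23830 circRNAs and the E2 library 25524, from 5928 and 6181 host genes. Exonic circRNAs made up 82.0% of those in DMSO and 81.3% of those in E2, and held 88.4% and 88.6% of the back-splice reads. The 5 circRNAs with the most reads summed over both libraries had ratios between 0.5 and 2. The largest number in a single library, 2950 reads in E2, belonged to a GSE1 circRNA that was unlisted in DMSO. The circRNA of ATXN7, whose protein is part of the SAGA chromatin complex, lay at 3:63898264-63898901 (hg19, exonic) and had 2575 reads in DMSO and 2255 in E2, a ratio of 0.747 (95% interval 0.706 to 0.791). The CDYL circRNA at 6:4891947-4892613 had 2219 and 2310 reads (ratio 0.888), and the ZKSCAN1 circRNA at 7:99621042-99621930 had 1895 and 2128 reads (ratio 0.958). Those of CAMSAP1 and BANP had ratios of 0.895 and 0.807.

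In all, 15238 circRNAs were listed in both libraries, 63.9% of those in DMSO and 59.7% of those in E2, and they held 87.5% and 84.4% of the back-splice reads. Another 8592 were listed in DMSO only and 10286 in E2 only. The smallest listed number was 2 reads, so an unlisted circRNA had 0 or 1 read only if nothing else kept it off the list. Each bound given below as "at least" is computed at a floor of 3 reads and holds only under that condition. Of the 2118 circRNAs with 20 or more reads in each library, 98.6% had a ratio between 0.5 and 2. The SD of their log2 ratios was 0.38, against 0.31 expected from counting. Abundant circRNAs were nevertheless missing from 1 of the lists more often than counting would give. Among circRNAs with 21 to 50 reads in E2, 10.3% were unlisted in DMSO (exact 95% interval 8.91 to 11.8), and among those with 101 to 200 reads 8.31% were (5.45 to 12.02). In the other direction the shares were 8.68% (7.34 to 10.2) and 2.85% (1.15 to 5.77).

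**Figure D1:**
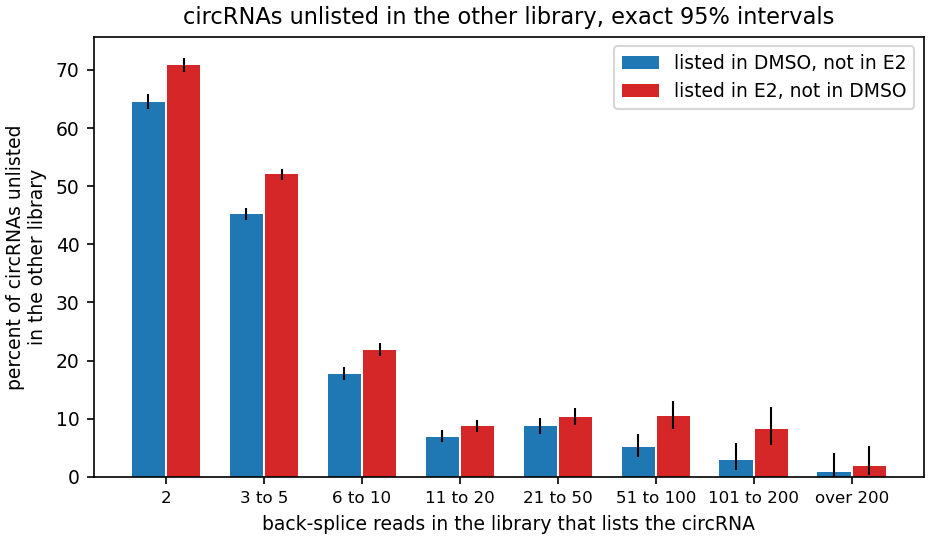
Share of circRNAs of 1 library (percent, y axis) that the other library did not list, by their back-splice reads in the library that lists them (x axis); blue, listed in DMSO and sought in E2; red, listed in E2 and sought in DMSO; lines, exact 95% binomial intervals. The share fell from 70.9% of E2 circRNAs with 2 reads to 8.68% at 11 to 20 reads, and was 10.5% at 51 to 100 reads.

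The series is named for circPGR, and circRNAs of PGR, the gene of the progesterone receptor and a classic estrogen target, were higher in the E2 library. All of them lay on the minus strand of chromosome 11 (hg19) and were annotated as exonic. The circRNA at 11:100922155-100996889 had 7 reads in DMSO and 28 in E2, a ratio of 3.41 (95% interval 1.46 to 9.25). The one at 11:100909851-100996889 had 7 and 25 reads, a ratio of 3.05 (1.28 to 8.34), and the one at 11:100912676-100996889 had 5 and 24 reads, a ratio of 4.09 (1.53 to 13.7). Another with the same upper end, 11:100933178-100996889, had 23 reads in E2 and was unlisted in DMSO, at least 6.54-fold higher under the condition given above (interval from 3.19 at 1 read). A further 2 PGR circRNAs, 11:100933178-100962607 and 11:100909851-100933483, were listed in E2 only, with 5 and 3 reads, and were below the minimum of 10 reads. Summed over the gene, with unlisted circRNAs adding no reads, there were 19 reads in DMSO and 108 in E2, a ratio of 4.85 (2.96 to 8.36). Over the 3 circRNAs listed in both libraries the sum was 19 and 77 reads, a ratio of 3.46 (2.07 to 6.05). The linear reads at these 3 junctions were 21, 1 and 8 in DMSO and 23, 5 and 18 in E2, in the order given above. The coordinates of circPGR itself are not given in the sources used here, so no value is assigned to it.

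**Figure D2:**
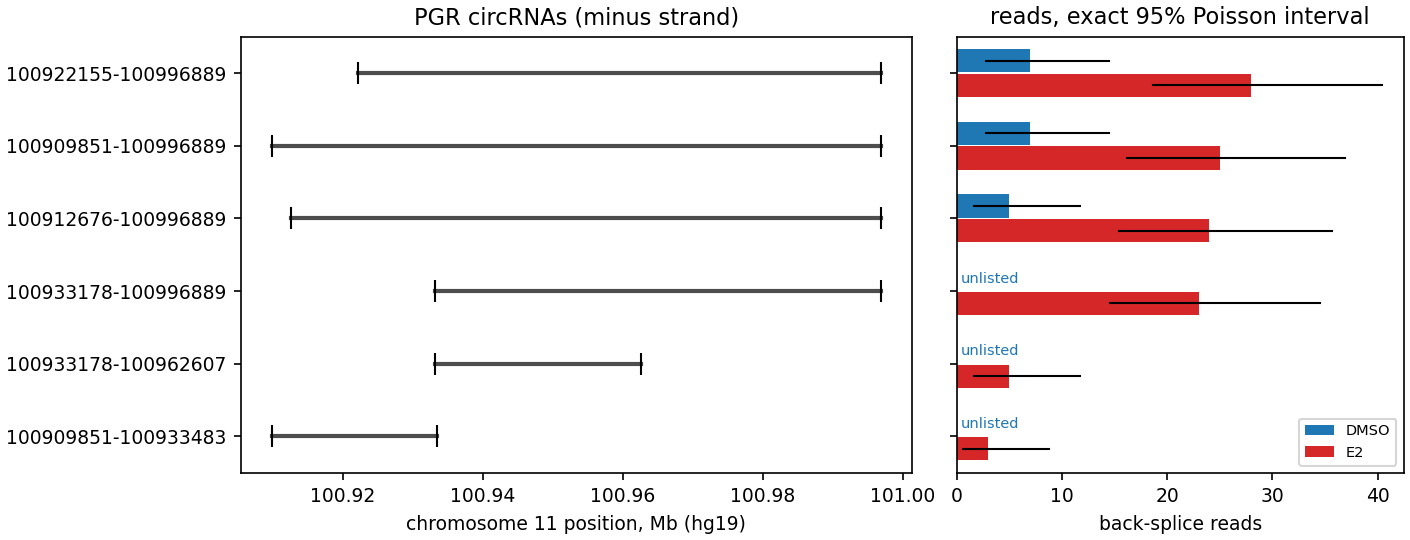
Left, the PGR circRNAs as spans between their back-splice ends on chromosome 11 (x axis, Mb, hg19); right, their back-splice reads (x axis) in DMSO (blue) and E2 (red) with exact 95% Poisson intervals. A group of 4 circRNAs shares the end at 100996889 and had 23 to 28 reads in E2, against 5 or 7 or an unlisted value in DMSO.

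Across all circRNAs the comparison asked which ones estradiol raised or lowered. Of 11147 circRNAs with 10 or more reads over both libraries, 875 were at least 2-fold higher in E2 and 780 at least 2-fold lower with an interval that excluded 1, so that 52.9% of those past the rule were higher. Simulated libraries without any change, with counting error alone, gave 133 higher and 139 lower. They held no other spread between libraries and no loss of abundant circRNAs from a list. The excess over them is thus not by itself an effect of estradiol. The circRNAs with the intervals farthest from 1 were each listed in 1 library. The GSE1 circRNA at 16:85667520-85667738 (exonic) had 2950 reads in E2 and was unlisted in DMSO, at least 839-fold higher under the same condition (interval from 451 at 1 read). KDM4C, the gene of a histone demethylase, gave 351 reads at 9:6880012-6893232, at least 99.8-fold higher if it had 0 or 1 read in DMSO. At the KDM4C circRNA 9:6849507-6893232, which shares its upper end and was singled out after its values were seen, linear reads were 358 in DMSO and 68 in E2, and the excess in DMSO was close to the 299 reads that an equal share would have given the unlisted circRNA. CCDC9 gave 241 reads at 19:47767860-47768203, at least 68.5-fold higher. DLG1, ACAP2, GAPVD1, DHX34 and PPIA followed, with 173 to 184 reads in E2. In the other direction the LARGE1 circRNA at 22:34157358-34161940 (intronic) had 390 reads in DMSO and was unlisted in E2, at least 152-fold lower. It was followed by RPPH1, the RNA component of RNase P, with 172 reads, and LOC100507412 on an unplaced sequence with 158. These 2 junctions had 4309862 and 3976016 linear reads in DMSO. Their circular share, 2 times the back-splice reads over that number plus the linear reads, was 0.00798% and 0.00795%. For the others named in this direction it was 31.9% to 97.9%. Next were DOCK1 with 149 reads, RPS6KB1 with 133, ETFA with 124, CARNMT1 with 120 and C3orf58 with 118.

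All 993 circRNAs that were listed in 1 library and had 10 or more reads passed this rule, 591 of them higher and 402 lower in E2. Of the 10154 circRNAs listed in both, 284 were higher and 378 lower (42.9% higher), against 109 and 135 in simulations of counting error alone. This restriction was chosen after seeing the data. Among circRNAs listed in both, TTC3 (21:38480692-38498443) had the interval farthest above 1, with 4 reads in DMSO and 49 in E2, a ratio of 10.4 (3.83 to 39.9). MYO9A had 3 and 31 reads, MYBL2, a cell cycle transcription factor, 2 and 24, and APPBP2 3 and 27. STYX and ATP6V1H each had 2 and 25 reads, CFDP1 3 and 23, and TBCK 5 and 30. Farthest below 1 was FAT1, an atypical cadherin (4:187627717-187630999, exonic), with 77 reads in DMSO and 14 in E2, a ratio of 0.155 (0.0810 to 0.276). ZMYM2, UBE3A, PIK3R3, RORA, SGPL1, SLC12A7 and NUP54 followed, with ratios from 0.0898 to 0.199 on 16 to 30 reads in DMSO.

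**Figure D3:**
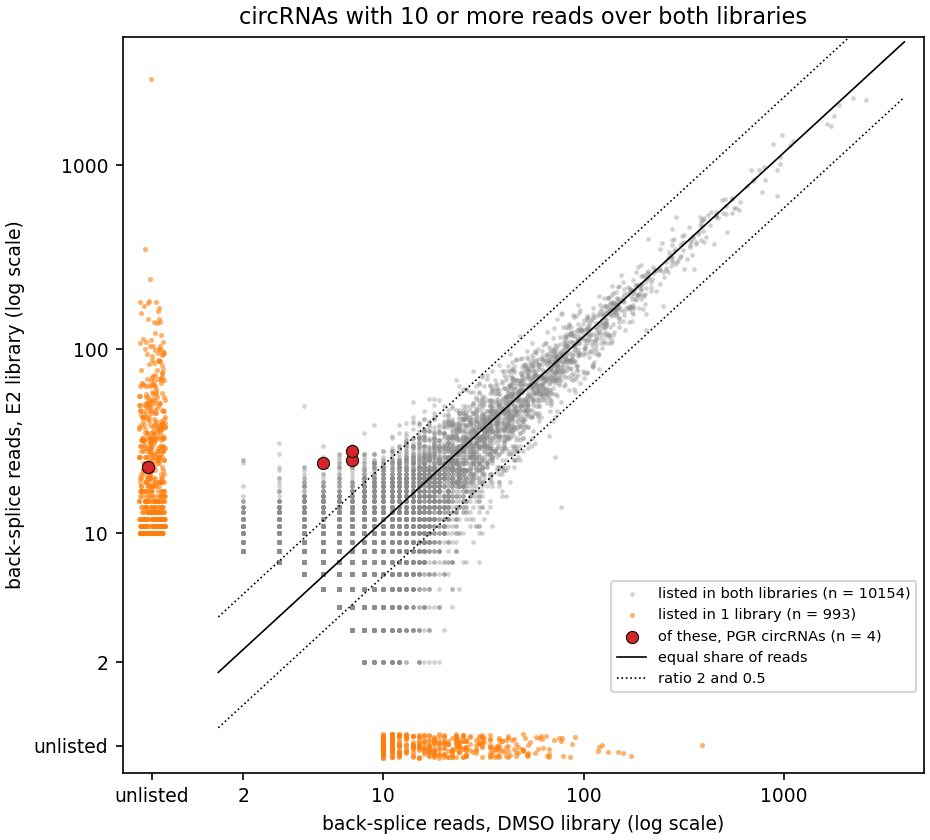
Back-splice reads per circRNA in DMSO (x axis) and E2 (y axis), both on log scales, for the 11147 circRNAs with 10 or more reads over both libraries; solid line, equal share of reads; dotted lines, ratios of 2 and 0.5. The 993 circRNAs listed in 1 library (orange, slightly scattered around the position marked unlisted) run along the axes up to 2950 reads, and 3 of the 4 PGR circRNAs shown (red) lie above the upper dotted line among circRNAs listed in both.

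Summed per host gene, 350 of 4688 genes were higher in E2 and 305 lower. Sums of host genes with a circRNA named above, such as GSE1 and RPPH1, were left out of the ranking that follows, some of them with more reads. Among the other genes, the higher sums with the most reads were those of PDCD11 (114 reads in DMSO and 287 in E2, ratio 2.15, interval 1.72 to 2.69), KCTD3 (ratio 2.17), PHF20 (2.22) and SOX13 (2.17). The lower ones among these were NPLOC4 (171 and 94 reads, ratio 0.469, interval 0.361 to 0.607), XRN2, a nuclear exoribonuclease (0.439), TSPAN15 (0.461) and CCT3 (0.372). Over circRNAs listed in both libraries only, 66 of 4007 sums were higher and 83 lower, and none of these 8 genes was past the rule: PDCD11 had a ratio of 0.965, SOX13 0.673 and XRN2 0.918. When scaled to total linear reads, 66.2% of the sums past the rule were higher, against 53.4% in the main scaling.

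Genes known to be induced by estrogen were then taken as a list. Its 31 measured host genes had a median log2 ratio of 0.20 in back-splice reads (interval 0.04 to 0.37), at the 97.5th percentile of random lists matched on reads, a description of these libraries. Of the 31, 6 were higher, none was lower and 25 did not pass. PGR had the highest sum of these. WWC1 (KIBRA) had 9 and 39 reads (ratio 3.70), SVIL 14 and 33 (2.01) and AFF1 12 and 31 (2.20), and CA12 and SLC7A5, named after their values were seen, were unlisted in DMSO with 15 and 11 reads in E2. The members with the most reads were close to even, with ratios of 1.05 for RHOBTB3, 1.09 for GFRA1 and 1.15 for THSD4. Over circRNAs listed in both libraries PGR alone of 27 genes was past the rule, and the median was 0.09 (percentile 94.96). Of the 7 measured estrogen-repressed genes 1 was higher, SORL1 (3 and 14 reads), and none was lower. SORL1 had 3 and 5 reads over circRNAs listed in both libraries, where none of 6 genes was past the rule. Over all listed circRNAs the median of the 7 genes was -0.32 (percentile 14.3), with ratios of 0.802 for ERBB2, 0.853 for BMP7 and 0.632 for ERBB3.

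The series title names cell cycle genes, and a list of these had a median log2 ratio of -0.07 over 71 host genes (percentile 26.5). Of them 8 were higher, among them FANCD2, a DNA repair gene (44 and 125 reads, ratio 2.42), RBL1 (2.09) and NCAPD2 (2.31), and 5 were lower, among them ORC2, an origin recognition gene (0.427). BRIP1, CEP192 and AURKA, the members with the most reads, had ratios of 1.01, 1.03 and 0.850. Over circRNAs listed in both libraries none of 66 was past the rule in either direction.

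Known circRNA hosts had a median of -0.08 over 46 genes (percentile 15.3), with 2 higher and 3 lower. ATXN7, CDYL and CAMSAP1 led it by reads, with ratios of 0.744, 0.887 and 0.904. FAT1 was lower with 79 and 18 reads (ratio 0.194, interval 0.110 to 0.327), all in circRNAs listed in both libraries, and its linear reads were 29 and 15 (ratio 0.490, interval 0.244 to 0.944). VRK1 (0.357) and CCDC66 (0.284) were lower and PHF21A (7.13) higher, but over circRNAs listed in both libraries their ratios were 0.742, 2.24 and 0.314. Under that restriction 1 of 46 genes was higher, CUL2, named after its values were seen (21 and 54 reads, ratio 2.19, interval 1.30 to 3.82), and 2 were lower, FAT1 and PHF21A. Luminal identity genes had a median of -0.12 over 20 genes (percentile 13.6), with MED1 (10 and 39 reads) and NCOA1 (unlisted in DMSO, 10 reads in E2) higher and none lower. Over circRNAs listed in both libraries none of 18 luminal genes was past the rule (MED1 1.60, interval 0.637 to 4.36) and the median was -0.03 (percentile 54.4). GRHL2, ESR1, the estrogen receptor gene, and ESRP1 had ratios of 1.02, 0.881 and 1.08. Genes of the 17q23 and 20q13 regions, amplified in MCF7, had a median of -0.13 over 36 genes (percentile 7.50). Of these CLTC, clathrin heavy chain, was higher, with 13 and 39 reads, and BRIP1, PPM1D and ATP9A had ratios of 1.01, 1.03 and 1.08. Genes of microRNA, RNA-binding and circRNA-forming proteins had a median of 0.01 over 20 genes (percentile 57.4). MBNL1 (2.71) and SRSF11 (7.68) were higher, XRN2 and HNRNPL (0.151) lower, and AGO2 and DROSHA had ratios of 1.03 and 1.26. With circRNAs listed in both libraries only, HNRNPL alone of 20 genes was past the rule (ratio 0.213), with ratios of 1.49 for MBNL1 and 3.84 (interval 0.795 to 36.5) for SRSF11, while CLTC of the amplified regions kept a ratio of 2.48.

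Markers of other cell types were near absent. The immune list had 1 measured host gene, DOCK8 (13 and 10 reads), with ITGAM at 2 reads in DMSO, and the stromal, mesenchymal and basal list had 1, COL5A1 (10 and 4 reads), with LAMC1 at 2 reads in each library and FBN1 at 2 reads in DMSO. Among abundant noncoding RNAs the median of 4 genes was -0.62 (percentile 4.91), from back-splice reads, which do not measure RNA quality. RPPH1 had 191 and 37 reads (ratio 0.165, interval 0.113 to 0.236), MALAT1 4 and 15 (3.20), NEAT1 114 and 94 (0.703) and RNA45S5 17 and 12 (0.602). RPPH1 and RNA45S5 had no circRNA listed in both libraries, and the MALAT1 sum over such circRNAs was 2 and 4 reads, so NEAT1 (0.842) was the only gene of this list measured under that restriction.

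Linear reads at the circRNA ends of estrogen-induced genes were higher in the E2 library. Back-splice reads of the list, over circRNAs listed in both libraries, had a median log2 ratio of 0.09 (interval -0.11 to 0.26). In the estrogen-induced list, 11 of 27 genes were higher in linear reads, none was lower and 16 did not pass. The examples that follow were chosen after their values were seen. Linear reads of TIPARP, a mono-ADP-ribosyltransferase, went from 25 to 169 (ratio 6.41, interval 4.19 to 10.2) and those of GREB1, a growth regulator and estrogen receptor cofactor, from 97 to 374 (3.65, interval 2.91 to 4.62). BCAS3 had a linear ratio of 3.88, KCNK5, a potassium channel gene, 3.86, and RARA, the retinoic acid receptor alpha gene, 2.15. The back-splice reads of circRNAs listed in both libraries had ratios of 1.28 for TIPARP, 1.04 for GREB1, 0.746 for BCAS3 and 0.924 for RARA. Over all listed circRNAs GREB1 had 72 and 127 reads, a log2 ratio of 0.59 (interval of the ratio 1.12 to 2.04), and 2 of the 11 genes were past the rule in both kinds of reads, WWC1 (circular ratio 3.70, linear 2.37) and SVIL (2.01 and 2.98). The list's median was 0.76 for linear reads (interval 0.47 to 1.24, percentile 100), and the median difference, circular minus linear, was -0.65 over 24 genes (interval -1.36 to -0.22, percentile 0). PGR had no linear value here because its junctions share an end with a circRNA listed in 1 library.

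**Figure D4:**
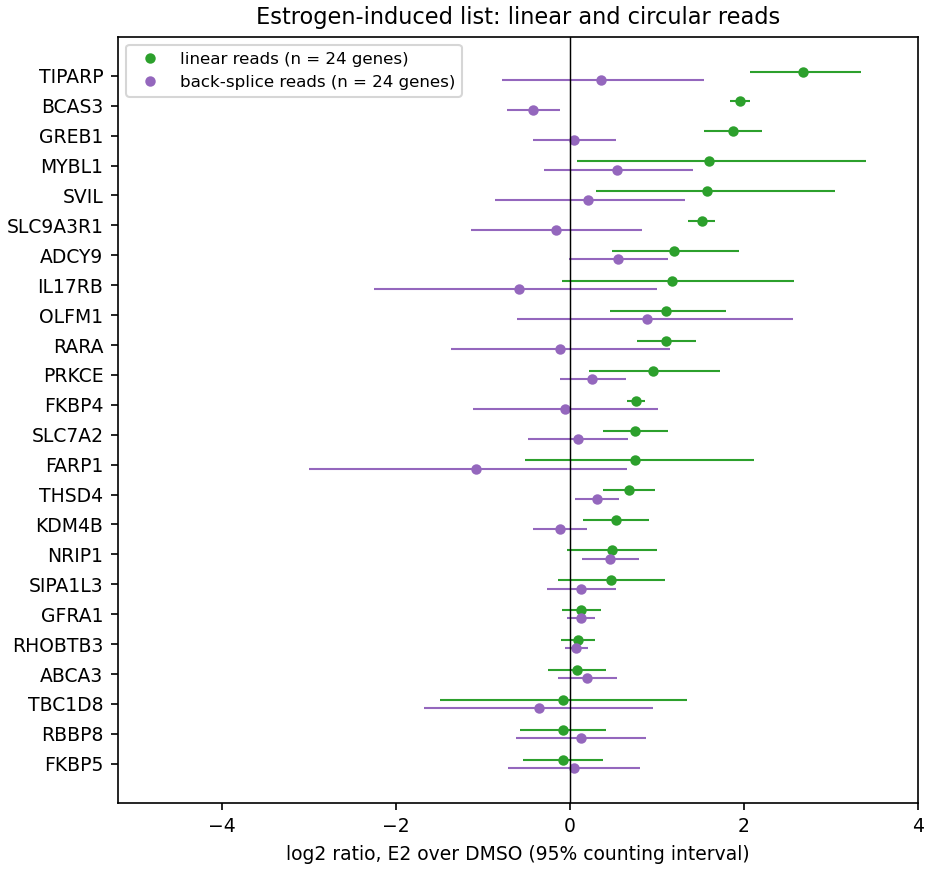
Log2 ratio of E2 over DMSO (x axis) for the 24 genes of the estrogen-induced list with values of both kinds, in linear reads (green) and in back-splice reads of circRNAs listed in both libraries (purple); lines, 95% counting intervals. Linear ratios reached 2.68 for TIPARP, 1.96 for BCAS3 and 1.87 for GREB1, where the circular ratios were 0.36, -0.42 and 0.05.

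In the other lists, linear medians were -0.30 for estrogen-repressed genes (6 genes; BCAS1 and ERBB3 lower), -0.01 for cell cycle genes (54), -0.11 for known circRNA hosts (38), -0.16 for luminal genes (19), 0.00 for the amplified regions (34) and 0.03 for RNA-binding and related genes (17). Over 3429 host genes with 20 or more linear reads, 149 were higher and 103 lower in E2. Of the 124 higher ones with enough back-splice reads none was higher in back-splice reads over circRNAs listed in both libraries, and 3 were over all listed circRNAs. Their median log2 ratios were 1.43 for linear reads and 0.00 for circular reads at circRNAs listed in both. These genes were chosen by a linear ratio of 2 or more, which fixed a linear median above 1 in advance and picks up counting noise. The circular reads were not so chosen, so the 2 medians do not measure how far circular reads follow linear ones. Of the 85 genes lower in linear reads with enough back-splice reads, 2 were lower in back-splice reads over circRNAs listed in both libraries. Over all listed circRNAs 6 were. Among all host gene sums, 66 of 4007 were higher and 83 lower over circRNAs listed in both libraries. Over all listed circRNAs 350 of 4688 were higher and 305 lower. Passes under the restriction were thus rare among host genes in general. Across 3049 host genes, which are not independent replicates, the 2 log2 ratios had a Spearman correlation of 0.0738. Counting error in both ratios weakens such a correlation, and the value was not corrected for it. The low value therefore cannot decide whether linear and circular changes were related. Linear reads were scaled by the median ratio of host genes, a choice made after seeing the data, and scaling by their sum instead shifts every linear log2 ratio by -0.12.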

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

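No paired analysis was possible because each group had 1 library, and no replicate could be left out. The alternatives with circRNAs listed in both libraries only, with reads counted once, with 0 reads for an unlisted circRNA and for linear reads were chosen after seeing the data. A minimum of 1 read could not be run, since the lists start at 2 reads. Of the alternatives to the counts, PGR ratios and list medians, 138 stayed within the interval or within 1.5 times the main value and 17 did not. For single named circRNAs and host genes 382 stayed, 24 moved and 6 turned around 1.

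At a minimum of 5 reads the libraries listed 11557 (DMSO) and 12880 (E2) circRNAs, 8044 of them in both, since fewer reads pass. Thinned to the DMSO total, E2 listed 23839 circRNAs on average, close to the DMSO number. Counts of circRNAs past the rule became 469 higher and 395 lower at a minimum of 20 reads, where fewer circRNAs can pass. They became 1178 lower (979 higher) both with no minimum and at 5 reads, where more can pass. The rule itself favors lower calls below 10 reads. The floor of 3 reads and the 1 read set for an unlisted circRNA were the same in both libraries, although E2 had 17.2% more back-splice reads. A circRNA listed in DMSO only therefore passes as lower on fewer reads than one listed in E2 only needs to pass as higher. How much of the turn to more lower than higher this makes up was not counted. With the 99% interval 556 were higher. Over circRNAs listed in both libraries the counts were 284 higher and 378 lower, and for host sums 66 and 83. For circRNAs, this setting left out the 993 listed in 1 library, which pass by construction, 591 of them higher and 402 lower. Simulations of counting error alone also gave fewer higher (109) than lower (135) among circRNAs listed in both. Why abundant circRNAs were listed in 1 library was not tested beyond the values under the observations that follow. Host sums at a ratio of 3 gave 203 higher and 183 lower, and 223 were higher with the 99% interval. Scaling to total linear reads raises every log2 ratio by 0.16, with 62.6% of circRNAs and 66.2% of host sums past the rule then higher, and moved the list medians of cell cycle genes to 0.0892 and of known circRNA hosts to 0.0790. Over circRNAs listed in both libraries the host ratios of PDCD11 (0.965), SOX13 (0.673), WWC1 (0.853), AFF1 (0.924) and PHF21A (0.314) fell below 1 and that of CCDC66 (2.24) rose above it; the alternative leaves out the circRNAs that made the difference. In simulated libraries 4-fold changes were recovered for 52.0% of circRNAs with means of 10 to 19 reads and 99.5% at 50 or more, so depth limits calls at low counts. Changes of 2-fold were recovered for 48.0% at 50 or more reads, where the rule's own ratio of 2 limits recovery.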

Other observations

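Outside the lists, linear reads of several other host genes were higher in E2, and the genes below were chosen after their values were seen. NTN1, the netrin 1 gene, had 11 linear reads in DMSO and 113 in E2 (ratio 9.73, interval 5.24 to 20.1), WNK1, a kinase gene, 41 and 242 (5.59), EWSR1, an RNA-binding protein gene, 42 and 231 (5.21) and SLC25A25, a mitochondrial carrier gene, 38 and 207 (5.16). DNASE2 had 272 and 1146 (3.99) and LARP1 101 and 416 (3.90). Lower were MAPK6 with 19 and 2 linear reads (ratio 0.0997, interval 0.0113 to 0.413), MAP3K4 with 55 and 12 (0.207), PGS1 with 67 and 24 (0.339) and MELK with 49 and 18 (0.348). Each value comes from 1 circRNA of the gene and need not hold for its other ends. At the PGS1 circRNA 17:76388557-76394432, left out for a shared end, linear reads were 187 in DMSO and 212 in E2, not lower. At the MAP3K4 circRNA 6:161443042-161471011, left out likewise, they were 12 and 2. The back-splice ratios over circRNAs listed in both libraries were 1.01 for WNK1, 0.948 for EWSR1, 1.03 for DNASE2, 1.08 for LARP1, 0.558 for MAPK6, 0.702 for MAP3K4, 0.957 for PGS1 and 0.871 for MELK. SLC25A25 had 4 and 14 such reads (ratio 2.99, interval 0.938 to 12.5) and NTN1 3 and 6 (1.71, interval 0.364 to 10.5).

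Of the tests below, the percentile bound for PGR against other host genes was written before its result was seen, and the others after. The look at host genes as far from 0 in either direction was not part of that bound. Abundant circRNAs listed in 1 library were the first pattern: 475 circRNAs with 20 or more reads, 291 of them in E2 and 184 in DMSO, were unlisted in the other library. Counting chance is argued against, since Poisson counts at equal shares give 0.00019 such circRNAs, and ends placed a few bases apart fit few of them, as 4.21% had a partner with both ends within 5 bases. A change of the whole host gene is argued against only for hosts with 10 or more reads in circRNAs listed in both libraries. The median log2 ratio of those circRNAs was 0.0294 higher for 199 hosts of E2-only than for 117 hosts of DMSO-only circRNAs (bootstrap interval -0.04 to 0.14). Other circRNAs of a host that were also listed in 1 library did not enter this comparison, so it cannot speak for them. Reads counted as linear in place of back-splice reads are argued against for the set, since at 353 shared ends the median excess of linear reads was -0.0164 of the reads expected (bootstrap interval -0.0488 to 0.0337). An excess of at least 0.5 was seen at 53 of these ends, KDM4C (0.980) among them, and in 562 of 4021 control comparisons at circRNAs of 20 or more reads listed in both libraries, a similar share, so a single end such as KDM4C does not settle it. A response of single junctions to estradiol stays open, and so does a loss of junctions from the deposited lists without a trace in linear reads.

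The second pattern was the higher reads of PGR circRNAs in E2. It did not rest on circRNAs listed in 1 library, since the sum over those listed in both had a ratio of 3.46 (interval 2.07 to 6.05). It lay at percentile 100 of the 200 host genes nearest in reads, of which none was as high. The series is named for circPGR, and how circPGR was chosen is not given in the sources used here. If it was chosen from these 2 libraries, the percentile gives no separate support. The bound of this test also looked at higher values alone, and FAT1, with 97 reads, lay farther from 0 at a log2 ratio of -2.36 against 1.79 for PGR. The linear reads of FAT1 were lower as well (29 and 15, ratio 0.490), but in the same 2 libraries. A treatment response and an unrelated difference between the libraries could each give this, so it does not decide what FAT1 stands for. A spread between these 2 libraries that is unrelated to the treatment stays open, since 1 library per condition cannot measure it. A rise of PGR circRNAs under estradiol, a known inducer of PGR, may be the reason, as a hypothesis that replicates would have to test.

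The third pattern was that linear reads of estrogen-induced genes were higher while back-splice reads were not to the same degree, with a median difference, circular minus linear, of -0.65 over 24 genes for circRNAs listed in both libraries. Too few back-splice reads to see a rise cannot be excluded as the reason. In 4 of the 24 genes, BCAS3, GREB1, SLC9A3R1 and TIPARP, the circular interval lay wholly below the linear one. That was 16.7% of the list (exact interval 4.74 to 37.4), against 3.07% of 3025 other host genes, and its lower limit did not reach 2 times the share of the others, the bound set for this test. This test replaced an earlier one, the upper bound of the median difference (-0.22), which only restates the pattern. A response to estradiol that differs between linear and circular RNA stays open and was not tested.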
